A study of Arabidopsis thaliana with 4 samples.

How the data were processed

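RNA from Col-0 rosette leaves was measured on 4 one-colour Affymetrix arrays, 2 for mock-treated and 2 for FAD-treated leaves. Per the labels' protocols, total RNA was copied into cDNA and then into biotin-labelled RNA with a 3' labelling kit. Per the submitters' processing notes the values came from GCOS, the array maker's software; its version and its summary algorithm are not given in the sources used here. The deposited values are 1 linear signal intensity per probe set and array. The 2% trimmed mean of the deposited intensity differed between arrays by 0.000764%, so the values had been scaled to a common mean. Such scaling cannot show a change in the total amount of mRNA. Detection calls and probe-level data were not analysed here. The lowest signal was 0.0832, and at such values the log2 scale is dominated by noise.

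The intensities were log2 transformed without an added constant. Quantile normalization was to be used only if the trimmed means differed by over 5%, so the deposited scaling was kept. The 64 control probe sets were set aside. Of the other 22746 probe sets, those with a mean log2 signal over the 4 arrays at or above the 40th percentile, a geometric mean signal of 63.59, were tested, which left 13648.

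Gene names came from the platform annotation of the probe sets, with symbols updated by gene ID through the TAIR10.1 reference table. The annotation gave 1 gene for 13513 probe sets and several genes for 503, and it did not list 8730, which are unnamed here. Of the 1-gene probe sets 13436 had a gene ID in the reference table and 77 did not. Of 411 different loci in 30 gene lists, 59 could be followed and 46 were tested; 9 lists had no named member, and 2 members were dropped because their symbol named another locus. The files name no genome build, so no coordinates are given. Where a gene had several probe sets, the one with the highest mean was used.

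FAD was compared with mock by limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a mean-variance trend, with the group as the only term and all 4 arrays in the fit. There were 2 residual and 5.43 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the tested probe sets with a threshold of 0.05. Fold changes are ratios of geometric means. An exact permutation test of 2 against 2 arrays cannot give a two-sided p under 0.333, so none was used. The labels call the replicates biological without saying whether they came from separate plants or days, so p-values measure only the spread between these samples. Gene lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene and 7286 genes in the background, and adjusted over 6 lists. Camera with an estimated correlation and fry, which asks whether a list's own genes move one way, were alternatives, and no list passed under any of the 3 methods in the main setting.

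The groups, the main tests, the alternatives, the gene lists and the rule for named genes were chosen before the data were examined. The rule took the 10 rising and 10 falling genes with the largest change among those that passed, had 1 gene name and had both FAD arrays on the same side of both mock arrays; free places went to the smallest unadjusted p in that direction. It also took each tested gene of the flavin list and up to 4 genes of each other list by the absolute moderated t. The lists covered flavin metabolism, B vitamins, singlet oxygen, hydrogen peroxide, antioxidant enzymes, heat shock, early immunity, salicylic acid, jasmonate, ethylene, abscisic acid, cold and DREB factors, touch and calcium, the clock, photosynthesis, flavonoids and light stress, detoxification, phosphate, cytokinin and auxin, sugar starvation and senescence, nitrate, reference genes, and markers of epidermis, guard cells, phloem, xylem, trichomes, myrosin cells, root and dividing cells. The singlet oxygen, abscisic acid, phosphate, sugar starvation and nitrate lists had no named member. The named flavonoid genes DFR and UF3GT were below the filter, with signals of at most 28.92 and 56.27.

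The alternatives were quantile normalization, median centring, 32 added to each signal before the log, no filter, a filter at the 60th percentile, no trend, a robust fit, array weights, the replicate number as a block, a test with each probe set's own variance alone and leaving out each array. The estimated correlation in the fits with a block or without 1 array was added after seeing the data. The fit was tested on simulated data: in 20 simulated comparisons of FAD against mock, each of 13648 probe sets with 200 changed, it called 21.5% of 2-fold, 81.4% of 4-fold and 94.6% of 8-fold changes, and 4.63% of its calls were unchanged probe sets. The simulated noise was normal, independent between probe sets and arrays, and had variances drawn from the prior of the same fit. These rates therefore need not hold for the real arrays, where same-numbered arrays deviated together. Figures were drawn with matplotlib 3.10.9.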

Results

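Transcript levels were measured in rosette leaves of 3-week-old Arabidopsis thaliana plants of the Col-0 accession. Flavin adenine dinucleotide (FAD) is the flavin cofactor of many oxidoreductases and is made in plants from riboflavin. Detached leaves lay for 1 h either on plain water, the mock treatment, or on 0.1 mM FAD. The incubation began 4 h into a light period of 16 h. There were 2 biological replicates of each treatment according to the labels, and each RNA sample was measured on 1 Affymetrix array, giving 4 arrays. The question was which transcripts differ when leaves are given FAD from outside for 1 h. Leaves before the treatment had no array, so a fall or rise is a difference from mock leaves and not a change over time.

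Each array gave 22746 probe set signals besides 64 control probe sets. The 2% trimmed mean was 500.1 on each of the 4 arrays, and the median signal lay between 118.4 and 133.7. Of the probe sets, 13648 passed the filter on dim signals and were tested, and 7344 of these carried a single gene name. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.23. Arrays of different treatment were about as alike as arrays of the same treatment. Across tested probe sets, which are not independent replicates, the correlation of log2 signals was 0.975 for both pairs of the same treatment and between 0.968 and 0.978 for pairs of different treatment.

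Transcripts of 4 named genes were lower in leaves on FAD than in mock leaves. Those of AFR (AT2G24540), an F-box protein of phytochrome A signalling, fell 4.46-fold, and those of HYH (AT3G17609), the bZIP transcription factor homologous to HY5, fell 3.98-fold. AT2G15020 fell 6.53-fold, and AT3G15310, a locus that the reference annotation lists as a pseudogene, fell 4.5-fold. One more probe set, which carried no gene name in the annotation used here, fell 8.64-fold. With the treatment as the only term, limma called 0 probe sets higher on FAD, with 414 higher at an unadjusted p under 0.05, and 1 without mock replicate 1.

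The AFR signal was 1094 ± 14.1 (SD, n = 2) in mock leaves and 232.6 and 258.3 on the 2 FAD arrays, a log2 fold change of -2.16 with a standard error of 0.18 (limma, Benjamini-Hochberg adjusted p = 0.029). HYH stood at 623.8 ± 35.6 in mock and 156.5 ± 2.8 in FAD leaves (SD, n = 2), a log2 fold change of -1.99 with a standard error of 0.20 (limma adjusted p = 0.0427). For AT2G15020 the log2 fold change was -2.71 ± 0.25 (SE, limma adjusted p = 0.0415), and for AT3G15310 it was -2.17 ± 0.22 (SE, limma adjusted p = 0.0454). For the unnamed probe set it was -3.11 ± 0.21 (SE, limma adjusted p = 0.0116). In these 5 probe sets both FAD arrays lay below both mock arrays. None of the 5 passed without the mean-variance trend, where limma adjusted p ran from 0.119 to 0.202.

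A further 6 genes, next in order of unadjusted p, had both FAD arrays below both mock arrays but did not pass the correction, with limma adjusted p between 0.0826 and 0.116. AT5G54130 stood at 359.9 ± 122 in mock and 51.55 ± 13.2 in FAD leaves (SD, n = 2), a ratio of mock over FAD of 6.89. A second probe set of the same gene, below the filter, had a log2 fold change of -1.48. The ratios of mock over FAD were 4.25 for AT1G64500, 4.17 for AT4G24700, 2.91 for AT1G76240, 2.38 for AT3G44450 and 2.37 for AT3G56290.

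With the treatment as the only term in limma and all 4 arrays, no gene passed in the upward direction. The 10 genes with the smallest unadjusted p among those higher on both FAD arrays had ratios of FAD over mock between 1.58 and 2.89, with limma adjusted p between 0.251 and 0.462. THI2.1 (AT1G72260), which encodes a thionin, an antimicrobial peptide, had the highest ratio of the 10, with a signal of 118.4 ± 53.8 in mock and 324.1 ± 26.7 in FAD leaves (SD, n = 2). AT3G20340 had a ratio of 2.23, AT1G08310 of 2.16, AT3G27210 of 2.08, AT1G08050 of 2.02 and AT2G28400 of 2. AT1G07870 had a ratio of 1.92, AT2G47550 of 1.89, AT3G05060 of 1.7 and AT5G25930 of 1.58.

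**Figure D1:**
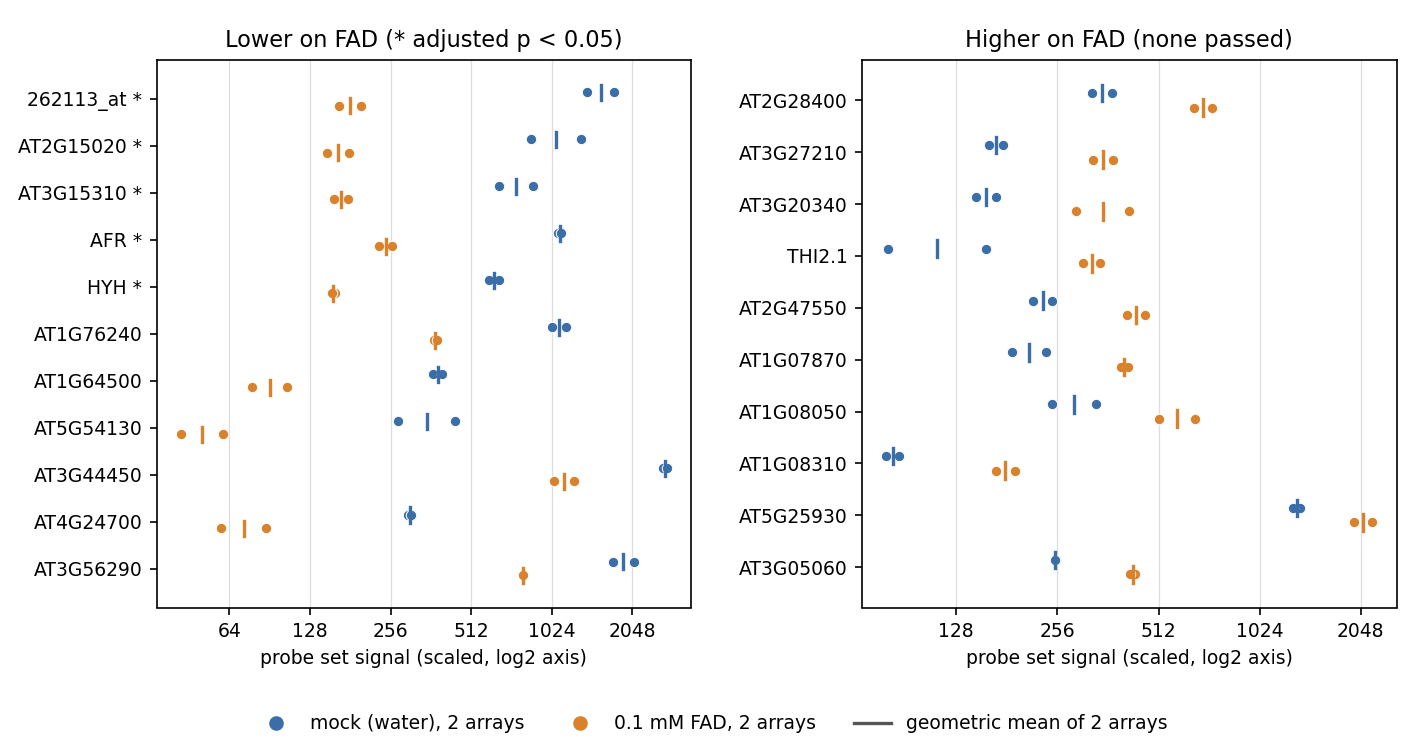
Signal of each named gene on each array, on a log2 axis, for genes lower on FAD (left, with the called probe set that is unnamed here) and genes higher on FAD (right); points are single arrays, 2 per treatment, and ticks are their geometric means. The 5 probe sets marked with an asterisk had a limma adjusted p under 0.05, and AFR fell 4.46-fold.

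Over all tested probe sets, limma with the treatment as the only term called 0 higher and 5 lower on FAD. With the replicate number added as a block it called 36 higher and 153 lower, but the labels do not say what that number shares. With the treatment as the only term there were 414 higher and 524 lower at an unadjusted p under 0.05, against 682.4 expected by chance over both directions. Splitting the arrays by replicate number instead gave 1106 such probe sets, against 938 for FAD against mock and 210 for the remaining split into pairs. The excess over chance is thus not particular to FAD. A test of each probe set with its own variance alone called 0 in either direction after Benjamini-Hochberg adjustment, with 471 higher and 391 lower at an unadjusted p under 0.05. Counted by size alone, 35 probe sets were at least 2-fold lower in both FAD arrays than in either mock array, and 5 were at least 2-fold higher. The other 2 ways to split the 4 arrays into pairs gave 10 and 0 lower, and 6 and 3 higher. Of the 35 lower probe sets 16 had a single gene name; among them, picked after their values were seen, were AT5G42760 at 11.8-fold lower and SWEET2, of the SWEET sugar transporter family, at 2.26-fold lower.

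The count of 5 lower was 11 with median centring, 2 with no filter, 2 with the filter at the 60th percentile and 0 without the mean-variance trend. With 1 array left out fewer were called, and not all of these were among the 5. AFR, HYH and AT3G15310 did not pass in those fits. Their log2 fold changes there ran from -2.23 to -2.08, from -2.05 to -1.94 and from -2.38 to -1.96, in that order. Rises of at least 2-fold outnumbered falls with no filter, 525 against 323, and without mock replicate 1, 142 against 66.

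The tested genes of flavin synthesis showed no detectable change. The flavin list held 13 genes for the synthesis and hydrolysis of riboflavin, FMN and FAD, of which 6 had a named probe set and were tested. All 6 are synthesis genes. FMN/FHY, FHY1, NUDX23, RIBA1, RIBA2, RIBA3 and PHS1 had no named probe set. The breakdown of flavins was therefore not covered, and their synthesis was covered only in part. PyrD (AT4G20960), the pyrimidine deaminase of riboflavin synthesis, stood at 401.8 ± 25.2 in mock and 468.3 ± 17.2 in FAD leaves (SD, n = 2), a log2 fold change of 0.22 with a 95% confidence interval from -0.21 to 0.66. AT4G11570, a phosphatase of the same pathway, had -0.24, with an interval from -0.60 to 0.12. COS1 (AT2G44050), the lumazine synthase, had -0.12, with an interval from -0.61 to 0.38. AT2G20690, riboflavin synthase, had 0.072, with an interval from -0.41 to 0.56. The FAD synthetase genes AT5G23330 and AT5G08340 had 0.17, with an interval from -0.41 to 0.76, and -0.10, with an interval from -0.67 to 0.46. Of the 6 genes 3 had a positive and 3 a negative value, and 0 passed in limma, over all tested probe sets or adjusted over the list alone, where the smallest unadjusted p was 0.156. The mean of the list was -6.03e-05 and its median -0.016, against a median of 0.05 over all tested probe sets (limma's camera, adjusted p = 0.701, and adjusted p = 0.761 with an estimated correlation).

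Genes induced by touch and calcium had the highest mean among the lists tested as sets, but the list did not pass. Of the 15 genes written in the list, 5 could be tested. Its 5 tested members, all calmodulin-like genes, had a mean log2 fold change of 0.49, and 4 of the 5 were positive (camera adjusted p = 0.133, and adjusted p = 0.761 with an estimated correlation). CML37 had 0.87 ± 0.29 (SE, limma adjusted p = 0.582), with 502 on FAD replicate 2 against 298.6 on FAD replicate 1. AT1G76640 had 0.80, CML23 had 0.61 and AT3G01830 had 0.24. None of the 5 passed in limma, also when adjusted over the list alone, and 1 had an unadjusted p under 0.05. Without FAD replicate 1 the list passed (mean 0.744, camera adjusted p = 0.00763), but not with an estimated correlation (adjusted p = 0.894), and over its 20 alternatives the adjusted p ran from 0.00763 to 0.924.

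Of the 21 genes written in the early immune list, 5 could be tested. These 5 all had positive log2 fold changes, with a mean of 0.27. They did not pass as a list (camera adjusted p = 0.184, and adjusted p = 0.761 with an estimated correlation). EXO had 0.49 ± 0.17 (SE, limma adjusted p = 0.582), the ubiquitin ligase genes PUB23 and PUB22 had 0.39 and 0.11, and the transcription factor gene WRKY53 had 0.22. In limma 0 passed singly or adjusted over the list alone, and 1 had an unadjusted p under 0.05. Without mock replicate 2 the list passed (mean 0.424, camera adjusted p = 0.0179), but not with an estimated correlation (adjusted p = 0.764), and over its 20 alternatives the adjusted p ran from 0.0179 to 0.924. Neither list passed for replicate 2 against replicate 1 (camera adjusted p = 0.0648, and adjusted p = 0.565 with an estimated correlation, for both). The early immune genes were higher on replicate 2 by a mean of 0.31 in mock and 0.18 in FAD leaves. The touch genes were higher there by 0.50 in FAD leaves, with -0.053 in mock leaves.

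The other 3 lists tested as sets did not pass (camera adjusted p = 0.701, and adjusted p = 0.761 with an estimated correlation, for each). Tested were 5 of 19 antioxidant enzyme genes, 4 of 19 cold and DREB genes and 5 of 22 photosynthesis genes. The 5 antioxidant enzyme genes had a mean of -0.021: the ascorbate peroxidase genes TAPX and SAPX had -0.31 and 0.28, and the glutathione reductase genes GR1 and GR had -0.15 and 0.12. The 4 cold and DREB genes had a mean of -0.12, which was 0.116 with no filter, with COR47 at 0.32, COR15A at -0.47, COR15B at -0.28 and the zinc finger gene STZ at -0.035. The 5 photosynthesis genes had a mean of 0.072, which was -0.0104 under quantile normalization; LHCB4.1 had 0.19, the Rubisco activase gene RCA 0.16, SBPASE -0.047 and PRK 0.033, the last turning to -0.0223 under quantile normalization and -0.00269 under median centring. In limma 0 members of these 3 lists passed, over all tested probe sets or adjusted over the list alone, and 0 had an unadjusted p under 0.05.

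**Figure D2:**
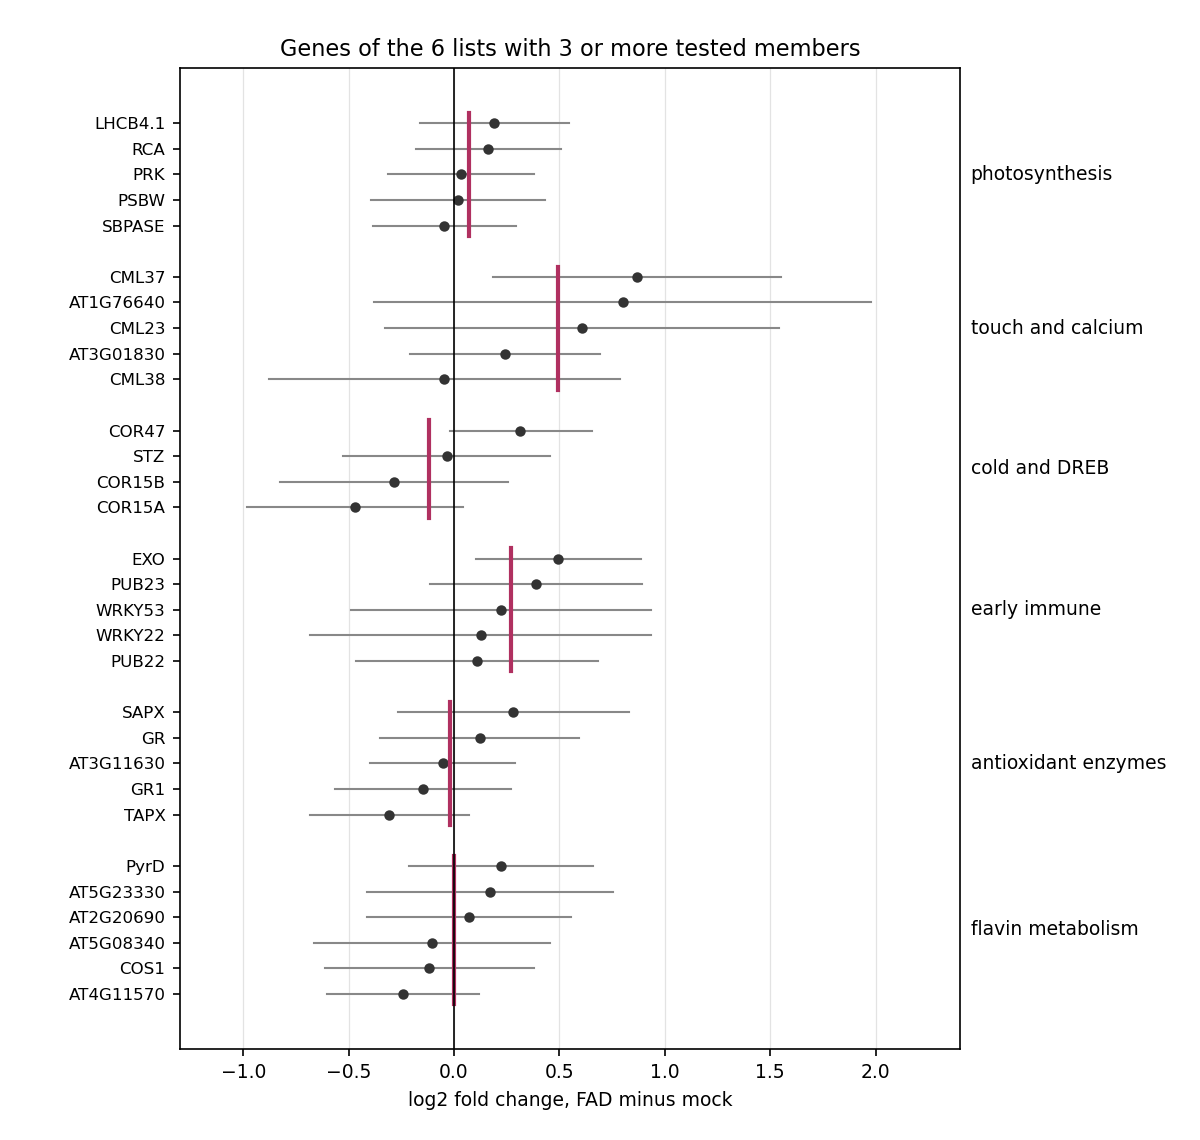
Log2 fold change (FAD minus mock) of each tested gene of the 6 lists with at least 3 tested members; points are limma estimates, grey lines their 95% confidence intervals, and red bars the mean of each list. The means run from -0.12 for cold and DREB genes, a sign that turns with no filter, to 0.49 for touch and calcium genes.

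The remaining pathway lists had at most 2 tested members, and none of these passed in limma over all tested probe sets or adjusted over the list alone. The circadian clock gene GI had a log2 fold change of -0.46 ± 0.21 (SE, limma adjusted p = 0.75). The auxin-conjugating enzyme gene GH3.3 had 0.92 ± 0.34 (SE, limma adjusted p = 0.636) and its relative WES1 had 0.18. The thiamin synthesis gene THIC had 0.11, and AT2G21640 of the hydrogen peroxide list, which also holds STZ, had 0.43. PDF1.2 and EIN3 of the ethylene list had -0.59 and -0.030, GRX480 of the salicylic acid list -0.13, and ORA47 of the jasmonate list -0.23. AER and UGT73B5 of the detoxification list had 0.26 and -0.16, AT5G48570 of the heat shock list 0.26, and the reference gene AT2G28390 0.044.

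Markers of leaf cell types gave few values. GLR3.3, a glutamate receptor-like channel gene in the phloem list, had a log2 fold change of -0.73 ± 0.20 (SE, limma adjusted p = 0.504). It passed adjusted over the list alone, where limma gave 0.0142 over 2 genes. SWEET11, the other tested phloem gene, had -0.022, which was 0.0144 under quantile normalization. FMA, a guard cell marker, had 0.58 ± 0.29 (SE, limma adjusted p = 0.763). The root marker EXPA7 reached at most 53.31 and the cell division marker HTR12 at most 54.8 on any array, and both were below the filter. No member of the epidermis, xylem, trichome and myrosin cell lists was named in the probe annotation used here.

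FAD replicate 2 stood apart in its control probe sets. On this array the 9 first-set probe sets for the spike-ins bioB, bioC, bioD and cre were lower than on the other arrays by a median factor of 5.6. The second set of 9 probe sets for the same spike-ins had a median log2 difference of 0.11. The 3' to 5' signal ratio of a transcript reads RNA integrity, and both actin ratios were lower on both FAD arrays: the first-set ratio was 31 and 33 in mock and at most 27.5 in FAD leaves, and the second-set ratio 5.42 and 5.56 in mock and 4.7 and 5.34 in FAD leaves. The GAPDH and ubiquitin ratios of both sets overlapped between treatments, so that 2 of 6 ratios separated them, where chance gives 33.33% for 2 against 2 arrays. FAD replicate 2 had the lowest second-set GAPDH ratio, 0.945 against 1.25 to 1.34 on the other arrays, and the lowest second-set ubiquitin ratio, 1.04 against 1.18 to 1.31.

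**Figure D3:**
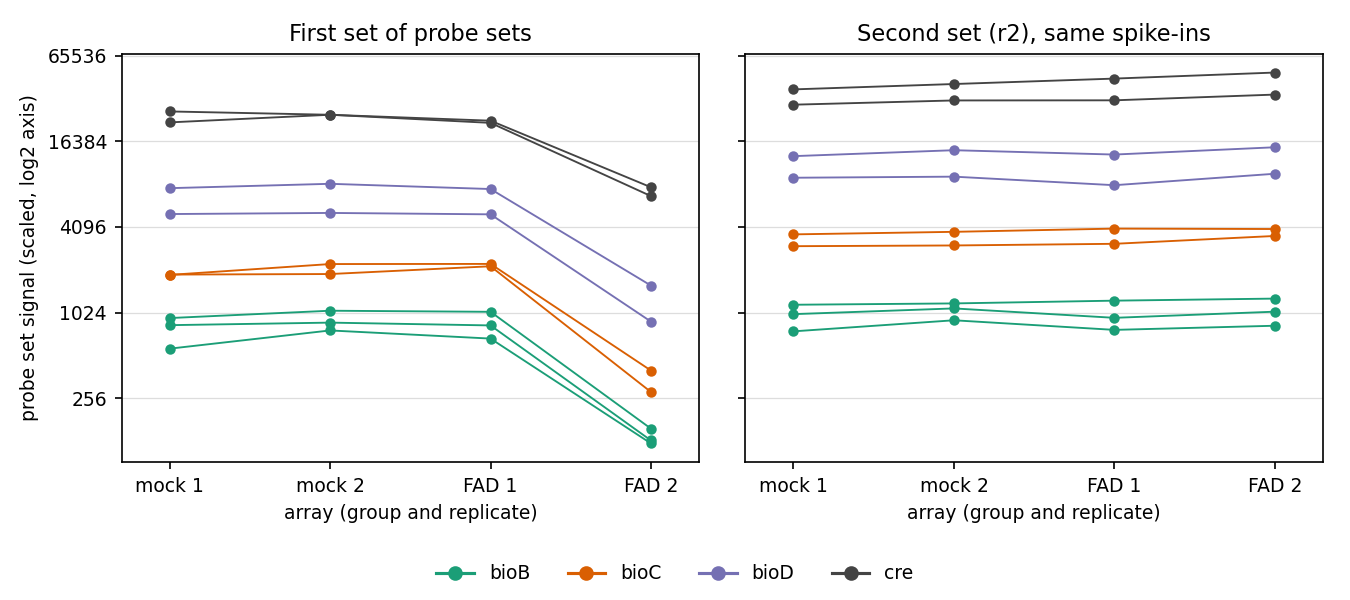
Signal of the spike-in control probe sets on the 4 arrays, on a log2 axis, for the first set (left) and the second set (right) of 9 probe sets each; lines join the values of 1 probe set. On FAD replicate 2 the first set was lower by a median factor of 5.6, and the second set had a median log2 difference of 0.11.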

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

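The estimated correlation in the fits with a block or without 1 array was chosen after seeing the data; the other alternatives were planned. The 10 named falls and the 10 named rises kept their direction with quantile normalization and median centring; the other alternatives could not turn them, since the rule took genes whose FAD and mock arrays did not overlap. The count of probe sets called lower, 5 in the main setting, was 11 with median centring, 2 with no filter, 2 with the filter at the 60th percentile, 0 with no trend and 0 with each probe set's own variance alone; it was 5 with quantile normalization, with 32 added, with the robust fit and with array weights. Over 13 alternatives AFR passed in 8 with limma adjusted p from 2.15e-05 to 0.182, HYH in 6 (8.99e-05 to 0.182), AT2G15020 in 7 (3.64e-06 to 0.201), AT3G15310 in 6 (7.63e-05 to 0.202) and the unnamed called probe set in 12 (1.14e-06 to 0.119). These 13 alternatives leave out the test with each probe set's own variance alone, in which none of these probe sets passed. The lowest adjusted p of each of these probe sets came from the fit with the replicate block. That fit leaves fewer residual degrees of freedom than the main fit, so it rests more on the prior variance. With the replicate block limma called 36 higher and 153 lower. In that fit the touch list (mean 0.494, camera adjusted p = 0.0231) and the early immune list (mean 0.268, camera adjusted p = 0.043) passed. So did 7 of the 10 named rises and all 10 named falls. With an estimated correlation in the same fit neither list passed (adjusted p = 0.74 for both). The labels do not say what a replicate number shares, and deviations of same-numbered arrays from their group means correlated at 0.219 across probe sets. With 1 array left out, the lone array of a group is assumed to vary like the others. Fewer probe sets were called lower in these fits, and not all of these were among the 5. Only without mock replicate 1 was any probe set called higher. The counts at least 2-fold lower and higher, 35 and 5, were 26 and 1 with 32 added, 323 and 525 with no filter, and 25 and 0 with the filter at the 60th percentile. With 1 array left out, which loosens the criterion, they ran from 66 to 162 and from 37 to 142, and rises outnumbered falls without mock replicate 1.

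Values that turned in sign were the photosynthesis mean (-0.0104) with quantile normalization, the cold and DREB mean (0.116) with no filter, PRK with quantile normalization (-0.0223) and median centring (-0.00269), and SWEET11 (0.0144) with quantile normalization. With 1 array left out the flavin mean ran from -0.0381 to 0.038 (0.0239 without mock replicate 2), the antioxidant mean from -0.0833 to 0.0414, the cold and DREB mean from -0.219 to -0.0189, the photosynthesis mean from 0.00428 to 0.14, the early immune mean from 0.112 to 0.424, passing without mock replicate 2 (adjusted p = 0.0179, and adjusted p = 0.764 with an estimated correlation), and the touch mean from 0.244 to 0.744, passing without FAD replicate 1 (adjusted p = 0.00763, and adjusted p = 0.894 with an estimated correlation). With 1 array left out these log2 fold changes crossed 0: COS1 from -0.315 to 0.0801, AT2G20690 from -0.0443 to 0.189, AT5G23330 from -0.033 to 0.373, AT5G08340 from -0.293 to 0.0836, STZ from -0.256 to 0.186, SAPX from -0.038 to 0.601, GR from -0.107 to 0.35, AT5G48570 from -0.347 to 0.866, WRKY53 from -0.198 to 0.642, PUB22 from -0.242 to 0.459, GRX480 from -0.676 to 0.409, PDF1.2 from -1.28 to 0.101, COR15B from -0.609 to 0.0389, AT1G76640 from -0.0969 to 1.70, SBPASE from -0.103 to 0.0102, PRK from -0.0658 to 0.132, UGT73B5 from -0.736 to 0.422, WES1 from -0.185 to 0.536, AT2G28390 from -0.0849 to 0.172 and SWEET11 from -0.45 to 0.406. Of 63 single probe sets with such a range, 20 crossed 0, 28 stayed within 1.5 times their value on 4 arrays, and 15 kept their sign but moved by more: THIC from 0.0233 to 0.193, AT2G21640 from 0.126 to 0.733, GR1 from -0.278 to -0.0187, PUB23 from 0.143 to 0.635, ORA47 from -0.445 to -0.01135, COR15A from -0.699 to -0.242, CML37 from 0.494 to 1.24, CML23 from 0.182 to 1.03, AT3G01830 from 0.0291 to 0.453, GI from -0.687 to -0.234, LHCB4.1 from 0.0797 to 0.302, RCA from 0.0662 to 0.26, AER from 0.114 to 0.408, GH3.3 from 0.53 to 1.31 and FMA from 0.246 to 0.921. Beyond the lower number of arrays or the other number of probe sets tested, the cause was not tested. Detection calls were not analysed here, so which signals lay above background is open.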

Other observations

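The tests of this part were chosen after the results were seen, except for the alternatives in scaling, added constant, filter and left-out arrays, which were planned. Gene families were formed from gene names, and 34 with at least 5 tested genes were compared with all other genes by camera; 0 passed, with 7 at an unadjusted p under 0.05 at the preset correlation and 0 with an estimated one. The calmodulin-like CML family (7 genes, 4 of them in the touch list) had a mean log2 fold change of 0.431 (limma's camera adjusted p = 0.159, and adjusted p = 0.903 with an estimated correlation). The 6 WRKY transcription factor genes, which include WRKY22 and WRKY53 of the early immune list, had a mean of 0.287 with 0 negative values (camera adjusted p = 0.216). The 67 plastid-encoded genes had a median of -0.0083, with 35 negative (camera adjusted p = 0.388).

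Falls were seen again on arrays not used to pick them more often than rises were, a difference that was not tested. Of 284 probe sets at least 2-fold lower on FAD replicate 2 than on mock replicate 2, 72.9% were lower on FAD replicate 1 than on mock replicate 1, and of 275 at least 2-fold higher, 58.5% were higher. With the pairs crossed the shares were 60.6% of 371 and 50% of 248. Picked on FAD replicate 1, the shares were 80.6% of 160 lower and 64.1% of 184 higher, and with the pairs crossed 58.8% of 177 and 45.4% of 421, so that single-array rises outnumbered falls on FAD replicate 1. The median log2 difference of the picked falls on the other arrays was -0.389 and -0.201 when picked on FAD replicate 2, and -0.705 and -0.302 when picked on FAD replicate 1.

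Falls of at least 2-fold outnumbered rises, 35 against 5, among the tested probe sets, although rises outnumbered falls with no filter and without mock replicate 1. The authors' scaling as the cause is argued against by falls staying at least 7.17 times as many as rises under quantile normalization and median centring, and noise of dim signals among the tested probe sets by 26 falls against 1 rise with 32 added to each signal. FAD replicate 2 alone cannot give the 35 falls, which are lower on both FAD arrays by definition, but a share of it in their excess stays open: falls were 70 against 49 rises without it and 162 against 37 without FAD replicate 1, and the weaker median of falls picked on it, -0.201 with a standard error of 0.055 that treats probe sets as independent, was below 0 by more than 2 standard errors but not below the bound of -0.25. A response to FAD stays open as well. Weaker light signalling may be part of it, since AFR and HYH belong there, but these 2 were named because they fell. Of 50 light-induced genes listed without these 2, only 2 were tested, LHCB4.3 and LIL3:1. Their mean log2 fold change was 0.0377, which is too few genes to decide. The 5 tested photosynthesis genes had a mean of 0.072, but that list was not written as a test of light signalling.

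The 4 arrays make 3 splits into pairs, too few for a share under 0.05; 1 of the 3, the real one, gave 5 probe sets past the threshold, and the highest other count was 0. At an unadjusted p under 0.05 the split of replicate 2 against replicate 1 gave 1106 probe sets, against 938 for FAD against mock and 210 for the crossed split, which points to a structure of the samples by replicate number. A difference in touch or wound response between the replicate sets may contribute, but 5 genes do not decide it: the touch and calcium list had an adjusted p = 0.0648 and was higher in replicate 2 only in FAD leaves. RNA quality that differs between the replicate sets stays open, since the ratios of 3' to 5' signal cannot decide it. Of 6 ratios, 2 separated the replicate numbers, in opposite directions. First-set GAPDH was 3.12 and 3.12 in replicate 1 against 3.65 and 3.53 in replicate 2. First-set ubiquitin was 2.32 and 2.91 against 2.3 and 2.25. The same count separated FAD from mock, with both actin ratios lower on both FAD arrays, and chance gives 33.33%. RNA quality that differs between the treatments therefore stays open as well. A shared day or batch is not given in the labels and was not tested.

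The first-set spike-in probe sets were lower on FAD replicate 2, with a median log2 difference of -2.48 ± 0.40 (SD over 9 probe sets). Less spike-in RNA in this hybridization is argued against by the second set for the same spike-ins, whose median log2 difference was 0.113 ± 0.072 (SD over 9 probe sets). A defect across the whole array is argued against by the ordinary probe sets: of 5755 bright ones, 0 were at least 4-fold lower there than on every other array, and the highest count on another array was 1. A local defect may remain, and array positions were not analysed here. No biological explanation was tested, since spike-ins are not leaf RNA.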
